A study of Mus musculus with 6 samples.

How the data were processed

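RNA-seq libraries of intestinal tissue from 3 WT and 3 Trmt6-/- mice with DSS-induced colitis were analysed, each library from a separate mouse per the series design. Per the labels, total RNA was extracted with a ZYMO Quick-RNA kit, converted to cDNA, amplified and made into libraries with the Vazyme TruePrep kit TD503. The libraries were amplified by PCR without molecular identifiers, so counting intervals cover counting error only. The deposited table holds raw counts per gene, and it is per the file headers the output of featureCounts 2.0.1 with paired reads, exons as features and genes as groups, on the GENCODE M23 annotation. No strand, multimapping or overlap option stands in the header, so counting was unstranded and left out reads mapped to several places or several genes. The submitters' processing notes name fastp and HISAT2, without versions, and the mm10 build. The deposited gene length column (unit: other) was written by featureCounts and was not used as a measurement. Library columns carry a group and an animal number but no replicate number, so each was assigned to its group by name, and not to a replicate.

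Counts were whole numbers summing to 15213972 to 16972758 per library. Gene symbols came from GENCODE M21, on the same GRCm38 assembly; 55154 of 55335 gene identifiers matched, and coordinates came from the deposited table. Within groups the Pearson correlation of log2 CPM ran from 0.933 to 0.973, and between groups from 0.905 to 0.959. No pair of libraries was a duplicate: within groups the chi-square per degree of freedom was 49.4 to 207. The gene with most counts took at most 2.70% of a library.

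Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with genotype as the only term, and p was adjusted by Benjamini-Hochberg over 14107 genes with a threshold of 0.05. The biological coefficient of variation was 0.345. CPM values use TMM-scaled library sizes, SD is over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of F. Ratios of genes with few counts have exact (Clopper-Pearson) 95% intervals from the summed counts of each group.

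Choices of model, filter, threshold, gene lists and the rule for naming genes were made before the data were examined. The rule named Trmt6, then, among genes past the threshold with a mean of at least 5 CPM and groups without overlap, the 12 with the largest log2 fold change in each direction. From each list it named up to 4 members past the threshold over all genes or, where none passed, the 2 with the highest CPM, and, since fewer than 20 genes passed in all, the 10 with the smallest p at 5 CPM or more. Some genes the rule names are not reported here. Other genes named were chosen after their values were seen. The rule's largest-change part skipped unnamed genes, immunoglobulin and T cell receptor segments.

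The 43 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists with at least 3 tested genes. The 38 were tRNA modification enzymes, aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, translation factors, integrated stress response, unfolded protein response, absorptive colonocytes, small intestinal enterocytes, goblet cells, Paneth cells, enteroendocrine cells, tuft cells and crypt stem cells and Wnt targets. They also held cell cycle, regenerating (fetal-like) epithelium, tight junctions and epithelial adhesion, epithelial antimicrobial and acute-phase, inflammatory cytokines and chemokines, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells, fibroblasts and extracellular matrix, smooth muscle, enteric neurons and glia and endothelium. The others were adipocytes, pancreatic acinar cells, squamous epithelium, type I interferon response, interferon-gamma response and antigen presentation, p53 targets and apoptosis, cell death by pyroptosis and necroptosis, fatty acid oxidation and ketogenesis, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation (nuclear) and immediate early and heat shock. The neutrophils, distal colon position (Hox), mitochondrially encoded, erythrocytes and sex-linked lists stayed outside this family because they had fewer than 3 tested genes or served as technical checks. Members past 0.05 were also counted with p adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

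Alternatives to the fit were RLE size factors, upper-quartile scaling, library totals, DESeq2 1.42.0, limma-voom without and with sample quality weights, robust dispersions, no low-count filter, a stricter filter (1 CPM in 3 libraries), a 2-fold minimum and each library left out in turn. Added after seeing the data were a regional index (mean log2 CPM of Fabp6, Slc10a2, Fgf15 and Slc51b minus that of Gata4, Lct, Cybrd1 and Fabp1) and a leukocyte index (mean log2 CPM of the T and NK cell list), each as a covariate. Some regional markers are also members of the enterocyte, colonocyte and fatty acid oxidation lists. The model was tested on simulated data, negative binomial counts with the means and dispersions of these libraries. Over 13754 genes it recovered 16% of genes given a 2-fold, 92% a 4-fold, 94% an 8-fold and 100% a 16-fold change. It made 3 false calls in 157, and 0 calls where no gene was changed.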

Results

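Gene expression was measured by RNA-seq in intestinal tissue of 6 mice in which colitis had been induced with dextran sulfate sodium (DSS), a polymer that injures the intestinal epithelium when given in drinking water. Wild-type (WT) and Trmt6-/- mice were compared, with 3 animals in each group. Trmt6 encodes the non-catalytic subunit of the enzyme that places 1-methyladenosine in tRNA, and Trmt61a encodes its catalytic partner. The series asks how loss of Trmt6 alters colitis, and its title places the effect in translation, whereas these libraries measure transcript abundance. No untreated animals were analysed here, so each value below compares genotypes within mice given DSS. The labels name intestinal tissue without a segment, and no gene of a distal colon list was abundant enough to test. Whether the sampled segment was inflamed was not tested. Few inflammatory genes were abundant enough to test in these libraries, 2 of 22 neutrophil genes and 7 of 32 cytokine and chemokine genes. The deposited counts per library summed to 16479870, 15213972 and 15367262 in the libraries named KO72, KO73 and KO75, and to 16972758, 16127970 and 16024317 in WT185, WT186 and WT187. Between 20470 and 21164 genes had at least 1 count in a library, and 14107 genes were tested. Values are given as mean ± SD of normalised CPM (library-scaled read counts) over 3 libraries, with the group labelled Trmt6-/- before WT. Log2 fold changes are estimate ± SE, positive where the libraries labelled Trmt6-/- were higher.

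Trmt6 transcript was not lower in the libraries labelled Trmt6-/-. The gene (ENSMUSG00000037376.14; GRCm38 chromosome 2, 132804207 to 132816055) stood at 39.8, 34.2 and 36.2 CPM in KO72, KO73 and KO75 and at 30.9, 18.7 and 23.1 CPM in WT185, WT186 and WT187. Its log2 fold change was 0.60 ± 0.21 (unadjusted p = 0.0256, adjusted p = 0.335), so the difference did not pass the test. These gene-level counts cannot show which exons were read, and none of the Trmt6 exon bases was shared with exons of another annotated gene. Trmt61a was measured at 12.1 ± 4.50 against 10.8 ± 4.35 CPM (adjusted p = 0.920). Because the targeted transcript went against the label, the groups are called the libraries labelled Trmt6-/- and WT throughout, and every direction rests on those labels.

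In all 6 libraries transcripts of small intestinal absorptive cells and goblet cells were abundant. The brush-border peptidase gene Anpep was measured at 7984 ± 2098 against 6169 ± 798 CPM and the lipoprotein gene Apob at 7977 ± 1978 against 5349 ± 2682 CPM. The goblet cell gene Fcgbp stood at 8470.5 ± 1971 against 6538 ± 1804 CPM, and none of these passed the threshold. The Paneth cell gene Defa24 stood at 2411, 1192 and 1257 CPM in KO72, KO73 and KO75 and at 1986, 219 and 912 CPM in WT185, WT186 and WT187. With no distal colon gene testable, the absorptive and Paneth cell values argue against distal colon as the segment of any library. Markers of position along the intestine differed between libraries of the same group. The ileal bile acid binding protein gene Fabp6 stood at 341, 267 and 16.7 CPM in KO72, KO73 and KO75 and at 543, 2.59 and 0.120 CPM in WT185, WT186 and WT187. Slc10a2, the ileal bile acid transporter, followed at 412, 283 and 62.8 CPM and at 224, 3.14 and 0.659 CPM. Lct, the lactase gene of the proximal small intestine, stood at 119, 771 and 664 CPM in the libraries labelled Trmt6-/- and at 756, 3192 and 2592 CPM in WT. Gata4, a transcription factor gene of the proximal small intestine, was measured at 116 ± 28.9 against 214 ± 57.5 CPM. The remaining index markers did not all follow this order. Ileal Slc51b stood at 75.6, 90.3 and 99.7 CPM in KO72, KO73 and KO75 and at 46.4, 54.0 and 31.3 CPM in WT185, WT186 and WT187. Proximal Fabp1 stood at 297, 1266 and 2931 CPM and at 511, 2616 and 769 CPM. Fgf15 reached at most 3.61 CPM, and Cybrd1 stood at 21.7 CPM in WT186 and 0.839 CPM in WT187. An index of ileal minus proximal markers was 0.61, -1.004 and -3.67 in KO72, KO73 and KO75 and -1.69, -7.41 and -6.04 in WT185, WT186 and WT187. It was used as a covariate in an alternative chosen after seeing the data. The mean log2 CPM of T and NK cell genes, a leukocyte index used in the same way, ran from 1.57 to 4.34 in the libraries labelled Trmt6-/- and from 2.90 to 4.82 in WT.

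**Figure D1:**
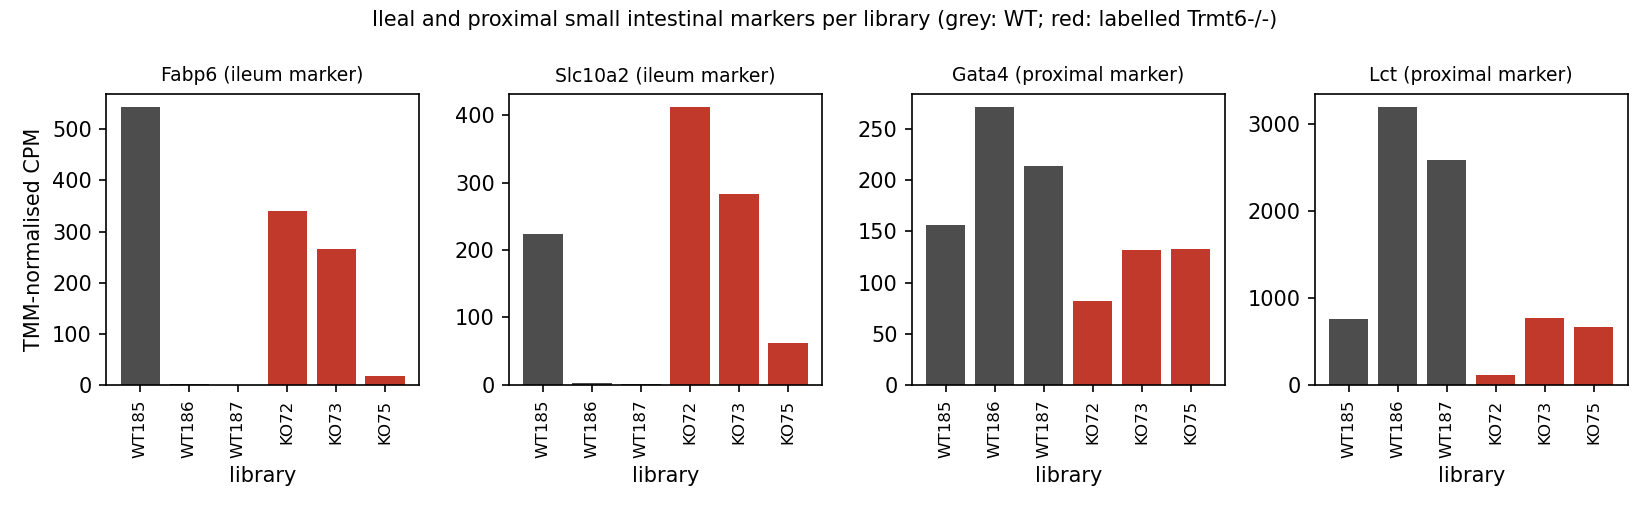
Normalised CPM (linear axes) of 2 ileal markers, Fabp6 and Slc10a2, and 2 proximal markers, Gata4 and Lct, with a bar for each library (grey, WT; red, labelled Trmt6-/-). WT185 carried 543 CPM of Fabp6 and WT186 and WT187 at most 2.59, while Lct was lower in WT185 (756) than in WT186 (3192) or WT187 (2592). The remaining index markers are not drawn and did not all follow this order, with Slc51b at 46.4, 54.0 and 31.3 CPM in WT185, WT186 and WT187.

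Genes of the integrated stress response (median log2 fold change 0.83), cholesterol synthesis (0.91), epithelial defence (0.96) and regenerating epithelium (1.34) were higher as groups in the libraries labelled Trmt6-/- with a preset correlation between genes, but none passed with an estimated one (lowest adjusted p = 0.206). Genes of antigen presentation (-1.18) and enteroendocrine cells (-0.96) were lower on the same terms (adjusted p = 0.446 and 0.0839 with an estimated correlation). Of 14107 genes tested, 6 changed between genotypes at an adjusted p below 0.05, 5 higher and 1 lower in the libraries labelled Trmt6-/-. Pgap1, which encodes a deacylase of glycosylphosphatidylinositol (GPI) anchors, rose to 123 ± 12.05 against 37.1 ± 0.382 CPM (log2 fold change 1.73 ± 0.13, adjusted p = 0.0347). Atf5, a transcription factor gene of the integrated stress response, rose to 83.5 ± 20.7 against 11.5 ± 2.87 CPM (2.86 ± 0.27, adjusted p = 0.0424). Myot, which encodes a sarcomere protein, was nearly restricted to the libraries labelled Trmt6-/- at 16.3 ± 8.06 against 0.0948 ± 0.0534 CPM (725 counts against 5, a ratio of 159 with a 95% exact counting interval of 67.8 to 491; adjusted p = 0.0347). Gml2, a gene of the Ly6 cluster on chromosome 15, showed a similar distribution at 12.4 ± 5.02 against 0.0575 ± 0.0529 CPM (550 counts against 3, a ratio of 201 with a 95% exact counting interval of 68.4 to 978; adjusted p = 0.0427). Ly6d, which encodes a GPI-anchored protein of the same cluster, lay under the expression minimum for naming and was chosen after its values were seen. It rose to 8.48 ± 2.11 against 0.332 ± 0.0516 CPM (396 counts against 17, a ratio of 25.5 with a 95% exact counting interval of 15.7 to 44.3; adjusted p = 0.0347). The gene that fell was Rtn4rl1, a Nogo receptor family member, at 5.42 ± 1.08 against 29.7 ± 3.88 CPM (-2.45 ± 0.22, adjusted p = 0.0424). Each of the 6 genes separated the groups without overlap, as did 2643 genes (18.7%) in all, where chance gives 10% on average over splits. A share above 10% is not tied to genotype by itself. There were other splits of the libraries with more genes at an unadjusted edgeR p below 0.05 (2059 and 1818, against 1706 in the real one). The counting intervals cover counting error only.

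On the GRCm38 assembly the changed genes lay at Pgap1 (chromosome 1, 54472994 to 54557684), Atf5 (chromosome 7, 44812256 to 44816658), Myot (chromosome 18, 44334074 to 44355724) and Rtn4rl1 (chromosome 11, 75193783 to 75267769). The remaining 2 were Ly6d (chromosome 15, 74762056 to 74763620) and Gml2 (chromosome 15, 74819071 to 74834871). The 5 next genes by p among those at 5 CPM or more did not pass. They were the zinc finger gene Zfp791 (2.75 ± 0.30), the ubiquitin ligase gene Rnf186 (-1.48 ± 0.16; 26.4 ± 3.97 against 73.5 ± 7.38 CPM) and the mucin gene Muc3a (1.95 ± 0.23; 128 ± 28.8 against 33.02 ± 6.07 CPM), followed by the periplakin gene Ppl (1.31 ± 0.15) and the metallothionein gene Mt1 (3.17 ± 0.39; 588 ± 277 against 65.5 ± 6.61 CPM). Their adjusted p ran from 0.0824 to 0.0838. At an unadjusted p below 0.05 there were 1706 genes, 868 higher and 838 lower. The calls were sensitive to single libraries: 0 genes passed without KO73, KO75, WT186 or WT187, 2 passed without WT185, and 6 passed without KO72, of which 2 were among the original 6. DESeq2 called 553 genes and limma-voom 0, and 0 passed with the regional index as covariate.

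**Figure D2:**
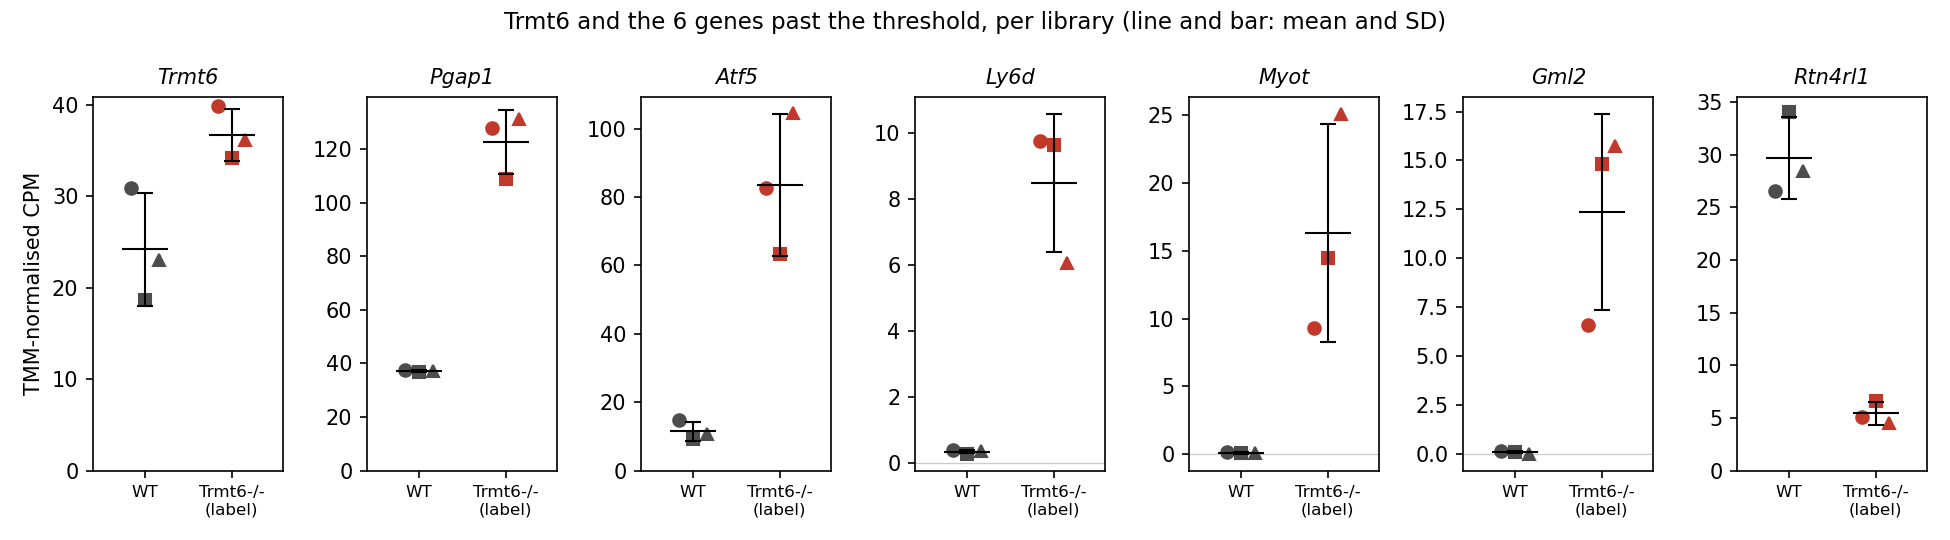
Normalised CPM of Trmt6 and of the 6 genes past the threshold, on linear axes, with a point for each library (grey, WT; red, labelled Trmt6-/-) and a line and bar for the mean and SD of 3 libraries. Trmt6 was not lower in the libraries labelled Trmt6-/- (36.7 ± 2.89 against 24.2 ± 6.18 CPM), and Pgap1 varied little within WT (37.1 ± 0.382 CPM).

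Gene lists fixed before the data were examined were tested as groups. With camera at its preset correlation, 19 of 38 lists passed, 12 toward higher and 7 toward lower expression in the libraries labelled Trmt6-/-. With an estimated correlation none of the 38 passed after adjustment, and 6 of the 19 had an unadjusted p below 0.05. The self-contained test fry passed 1 list, the enteroendocrine markers (adjusted p = 0.0172). Other ways of dividing the 6 libraries into 3 and 3 called up to 19 lists as well. The counts of members that passed when adjusted over the list alone are given beside each list. These counts are no safeguard by themselves. Other divisions reached 29 for cell cycle and 17 for T and NK cells, against 0 for each in the real one. Over all genes tested, Atf5 was the only list member past the threshold. Members named beyond the 2 most abundant of a list were chosen after their values were seen. Where a list passed or ceased to pass without a library, the value in parentheses is its adjusted p without that library. Other fits are 9 alternative scalings, models and low-count filters without a covariate.

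**Figure D3:**
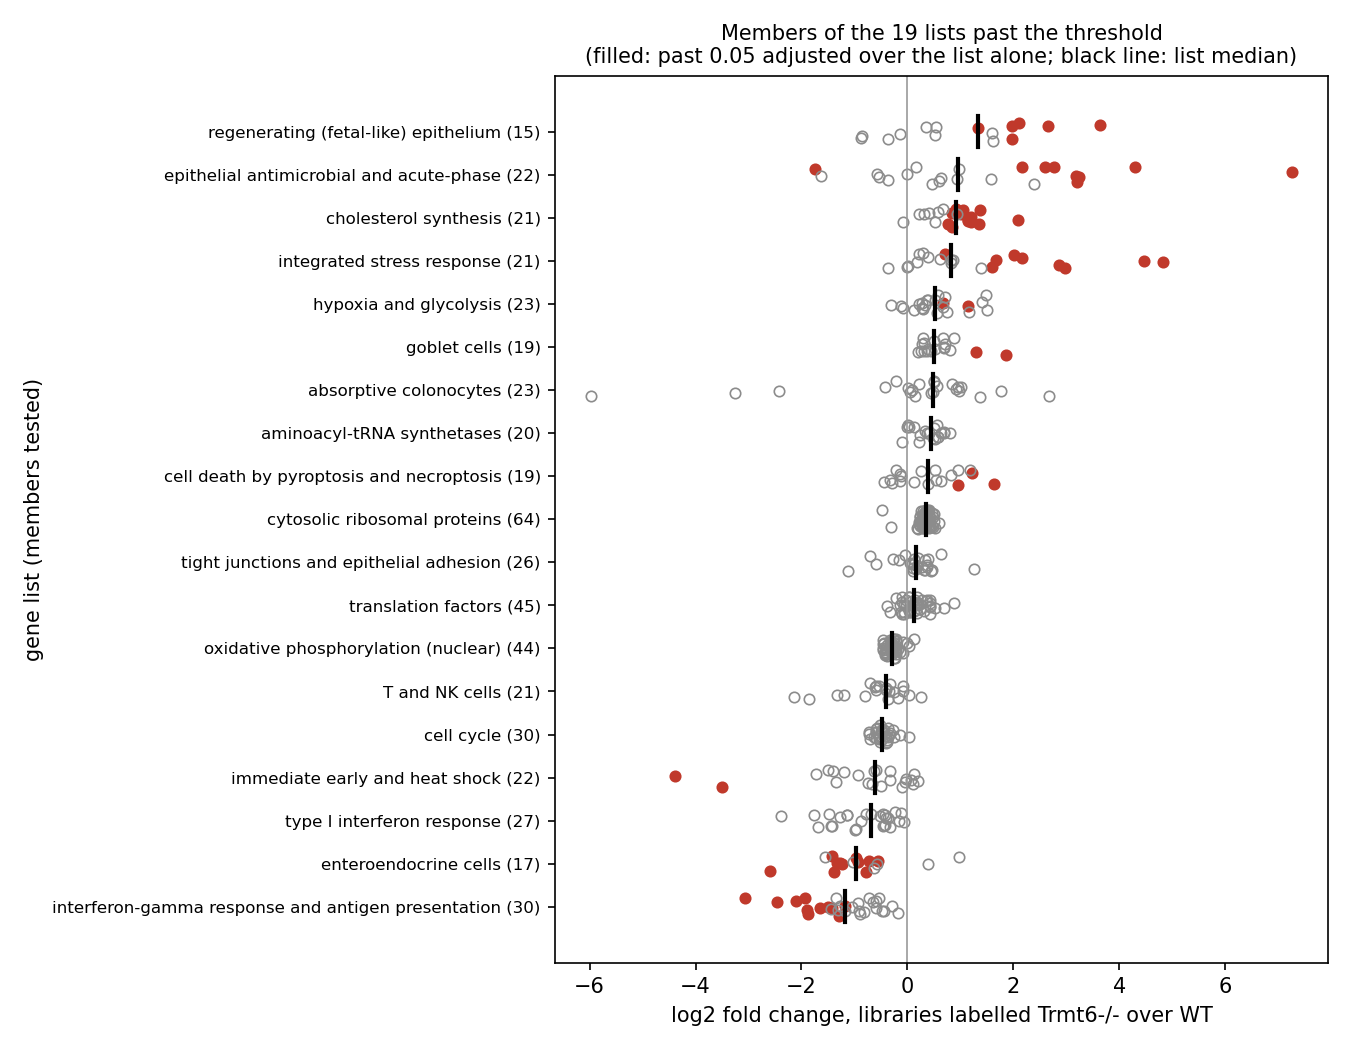
Log2 fold change (horizontal axis, libraries labelled Trmt6-/- over WT) of each tested member of the 19 lists past the threshold (vertical axis, with the number of members tested), with the list median as a black line and members past 0.05 adjusted over the list alone filled. The medians run from -1.18 in the interferon-gamma and antigen presentation list to 1.34 in the regenerating epithelium list.

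Genes of the integrated stress response, the ATF4-driven programme induced by amino acid shortage and other stresses, rose as a group in the libraries labelled Trmt6-/-, in which Trmt6 was not lower. Of 21 members tested, 9 rose and 0 fell adjusted over the list alone, and 12 did not pass (median log2 fold change 0.83, adjusted p = 1.9e-15; adjusted p = 0.206 with an estimated correlation). Besides Atf5, these included Chac1, which degrades glutathione (4.83 ± 0.68; 11.8 ± 4.55 against 0.399 ± 0.302 CPM), and the cystine transporter gene Slc7a11 (4.46 ± 0.71; 10.6 ± 3.44 against 0.458 ± 0.410 CPM). Also among the 9 were Trib3 (2.02 ± 0.42; 25.7 ± 6.19 against 6.37 ± 3.35 CPM) and the serine synthesis gene Psat1 (2.17 ± 0.51; 64.1 ± 25.4 against 14.2 ± 7.67 CPM). Asparagine synthetase Asns (1.68 ± 0.40; 105 ± 36.2 against 32.6 ± 15.95 CPM) and Atf4 itself (0.71 ± 0.21; 264 ± 56.8 against 162 ± 23.1 CPM) rose as well. Their adjusted p over the list ran from 3.2e-04 for Atf5 to 0.0389 for Atf4. The number of members past the threshold was 6 without KO72 or KO75, 8 without WT186, 9 without KO73 or WT187 and 11 without WT185. It was 7 with the regional index as covariate and 6 to 12 under other fits.

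Genes of the translation machinery had smaller list medians. Aminoacyl-tRNA synthetases, several of which are ATF4 targets, passed toward higher expression (20 tested, median 0.45, adjusted p = 2.5e-05; adjusted p = 0.724 with an estimated correlation), with 0 members past the threshold adjusted over the list alone and 7 without WT185. Nars was measured at 463 ± 110.1 against 287 ± 23.4 CPM, Qars at 217 ± 6.56 against 184 ± 19.9 CPM and Gars at 183 ± 34.04 against 104 ± 25.05 CPM. Cytosolic ribosomal protein genes passed with a small median of 0.35 (64 tested, 62 above 0, adjusted p = 2.0e-07; adjusted p = 0.817 with an estimated correlation) and 0 members past the threshold alone, and did not pass without WT186 (0.0835). Rplp0 stood at 1521 ± 83.4 against 1134 ± 486 CPM and Rpl4 at 1214 ± 88.5 against 942 ± 321 CPM. Translation factors passed at a median of 0.12 (45 tested, adjusted p = 0.0414; adjusted p = 0.869 with an estimated correlation), with 0 members alone, and did not pass without KO72 (0.293), KO75 (0.103), WT186 (0.778) or WT187 (0.174) or with the leukocyte index as covariate (adjusted p = 0.184). It did not pass either with library totals (adjusted p = 0.107) or with sample quality weights (adjusted p = 0.0659). Eef1a1 stood at 7048 ± 413 against 5221 ± 1527 CPM and Eef2 at 3763 ± 387 against 2898 ± 646 CPM. With the regional index as covariate the ribosomal and translation factor lists turned direction (adjusted p = 0.838 and 0.545) and the synthetases no longer passed (adjusted p = 0.117). The 45 tRNA modification enzymes did not pass (median 0.024, adjusted p = 0.865) except toward lower expression with that covariate (adjusted p = 0.0173). Nsun2 was measured at 106 ± 21.6 against 105 ± 30.5 CPM and Elp2 at 56.6 ± 4.83 against 53.5 ± 5.64 CPM. The 22 genes of the unfolded protein response did not pass either (median 0.013, adjusted p = 0.865). Calr was measured at 777 ± 172 against 667 ± 85.2 CPM and Hspa5 at 680.4 ± 213 against 666 ± 130.4 CPM.

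Cholesterol synthesis genes rose together in the libraries labelled Trmt6-/-. Of 21 members, 13 rose and 0 fell adjusted over the list alone (median 0.91, adjusted p = 1.0e-15; adjusted p = 0.354 with an estimated correlation). They included Hmgcs1 (1.15 ± 0.26; 434 ± 32.7 against 195 ± 66.8 CPM). Sqle (1.35 ± 0.39; 256 ± 19.2 against 100.4 ± 58.6 CPM), Hsd17b7 (1.37 ± 0.25) and Fdps (2.10 ± 0.49) rose too, as did the sterol carrier gene Stard4 (0.76 ± 0.16; 490.5 ± 18.1 against 289 ± 10.3 CPM). The count rested on single libraries, with 0 without KO75 or WT187, 8 without KO72, KO73 or WT186 and 18 without WT185. It was 9 with the regional index as covariate and 8 to 19 under other fits. Hypoxia and glycolysis genes also passed toward higher expression (23 tested, median 0.53, adjusted p = 7.5e-07; adjusted p = 0.206 with an estimated correlation). Of these the glucose transporter gene Slc2a1 (1.14 ± 0.23; 29.6 ± 6.40 against 13.4 ± 2.16 CPM) and Pdk1 (0.67 ± 0.13; 113 ± 4.12 against 71.1 ± 6.98 CPM) rose adjusted over the list alone, and 21 did not pass. Ldha was measured at 1806 ± 373 against 1561 ± 301 CPM and Gapdh at 1497 ± 269 against 1376 ± 519 CPM. The count was 0 without KO72, KO75 or WT187, 1 without KO73, 2 without WT185 and 6 without WT186. It was 5 with the regional index as covariate and 0 to 10 under other fits, with 0 for library totals and 7 for upper-quartile scaling, DESeq2 and limma-voom.

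Nuclear genes of oxidative phosphorylation passed toward lower expression by a small margin (44 tested, 42 below 0, median -0.28, adjusted p = 7.7e-05; adjusted p = 0.861 with an estimated correlation). None of the 44 members passed adjusted over the list alone, the list did not pass without KO72 (0.127) or WT186 (0.0590), and with the regional index as covariate the list turned direction without passing (adjusted p = 0.764). Atp5b was measured at 1862 ± 369 against 2346 ± 263 CPM and Atp5a1 at 1805 ± 361 against 2104 ± 268 CPM. Fatty acid oxidation and ketogenesis did not pass (24 tested, adjusted p = 0.865), with a median of -0.15, a mean of 0.044 and a test direction toward lower expression. Of its members Bdh1, a ketone body dehydrogenase, fell adjusted over the list alone (-0.81 ± 0.15; 108 ± 10.1 against 190.4 ± 13.8 CPM) and 23 did not pass. The number of members past the threshold was 0 without KO72, KO73, KO75 or WT185, 2 (1 higher, 1 lower) without WT187 and 3 (2 higher, 1 lower) without WT186. It was 1 to 7 under other fits, in both directions. The list passed toward higher expression without WT186 (0.0262) and with the regional index as covariate (adjusted p = 0.00536). Fabp1 was measured at 1498 ± 1332 against 1299 ± 1148 CPM.

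Interferon-gamma response and antigen presentation genes fell in the libraries labelled Trmt6-/-, again with Trmt6 not lower. Of 30 members, 11 fell and 0 rose adjusted over the list alone, and all 30 had a log2 fold change below 0 (median -1.18, adjusted p = 1.4e-15; adjusted p = 0.446 with an estimated correlation). The MHC class II transactivator gene Ciita fell by 1.87 ± 0.43 on the log2 scale (24.9 ± 9.93 against 91.2 ± 35.8 CPM). Its targets H2-Aa (-2.11 ± 0.59; 118 ± 51.1 against 509.8 ± 292 CPM) and H2-Ab1 (-1.90 ± 0.49; 133 ± 48.7 against 498 ± 249 CPM) fell with it. The interferon-inducible GTPase gene Igtp (-3.06 ± 0.68; 7.78 ± 4.57 against 64.5 ± 39.1 CPM), the immunoproteasome gene Psmb9 (-1.49 ± 0.32) and the peptide transporter gene Tap1 (-1.30 ± 0.39) also fell. H2-K1 was measured at 912 ± 247 against 1432 ± 554 CPM and B2m at 762 ± 220.1 against 1422 ± 573 CPM. The count was 0 without KO72, KO73, KO75, WT186 or WT187 and 18 without WT185. It was 10 to 24 under other fits and 0 with the regional index as covariate, under which the list kept its direction with a median of -0.34 (adjusted p = 0.0135). Within WT, H2-Aa stood at 179 CPM in WT185, the WT library with the highest Fabp6, and at 731 and 620 CPM in WT186 and WT187.

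The type I interferon response passed in the same direction, with all 27 members below 0 (median -0.69, adjusted p = 2.8e-08; adjusted p = 0.446 with an estimated correlation). None of the 27 passed adjusted over the list alone, against 7 without WT185 and 0 to 13 under other fits. Ifit1 was measured at 5.31 ± 2.65 against 27.8 ± 17.3 CPM, Oas3 at 8.99 ± 3.42 against 30.6 ± 16.5 CPM, and the more abundant Ifih1 at 72.8 ± 10.2 against 93.9 ± 23.4 CPM and Stat2 at 54.5 ± 15.001 against 73.97 ± 22.3 CPM. The list did not pass with the regional index as covariate (adjusted p = 0.307). T and NK cell genes passed toward lower expression (21 tested, median -0.41, adjusted p = 0.0336; adjusted p = 0.869 with an estimated correlation), with 0 members past the threshold alone. Gzma stood at 167 ± 166 against 254 ± 178 CPM and Cd8a at 69.1 ± 64.9 against 72.6 ± 49.9 CPM. The list did not pass without KO73 (0.0646) or with DESeq2 (adjusted p = 0.0870). It turned toward higher expression without passing when KO72 (0.626) or WT187 (0.821) was left out and with the regional index as covariate (adjusted p = 0.110). Of 32 inflammatory cytokine and chemokine genes, 7 were abundant enough to test and the list did not pass (median -0.74, adjusted p = 0.154) except without KO75 (2.0e-04) or WT185 (4.5e-04) and with sample quality weights (adjusted p = 0.0196). Ccl5 stood at 62.1 ± 57.2 against 104 ± 83.3 CPM and Lif at 8.34 ± 1.35 against 8.69 ± 1.69 CPM.

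**Figure D4:**
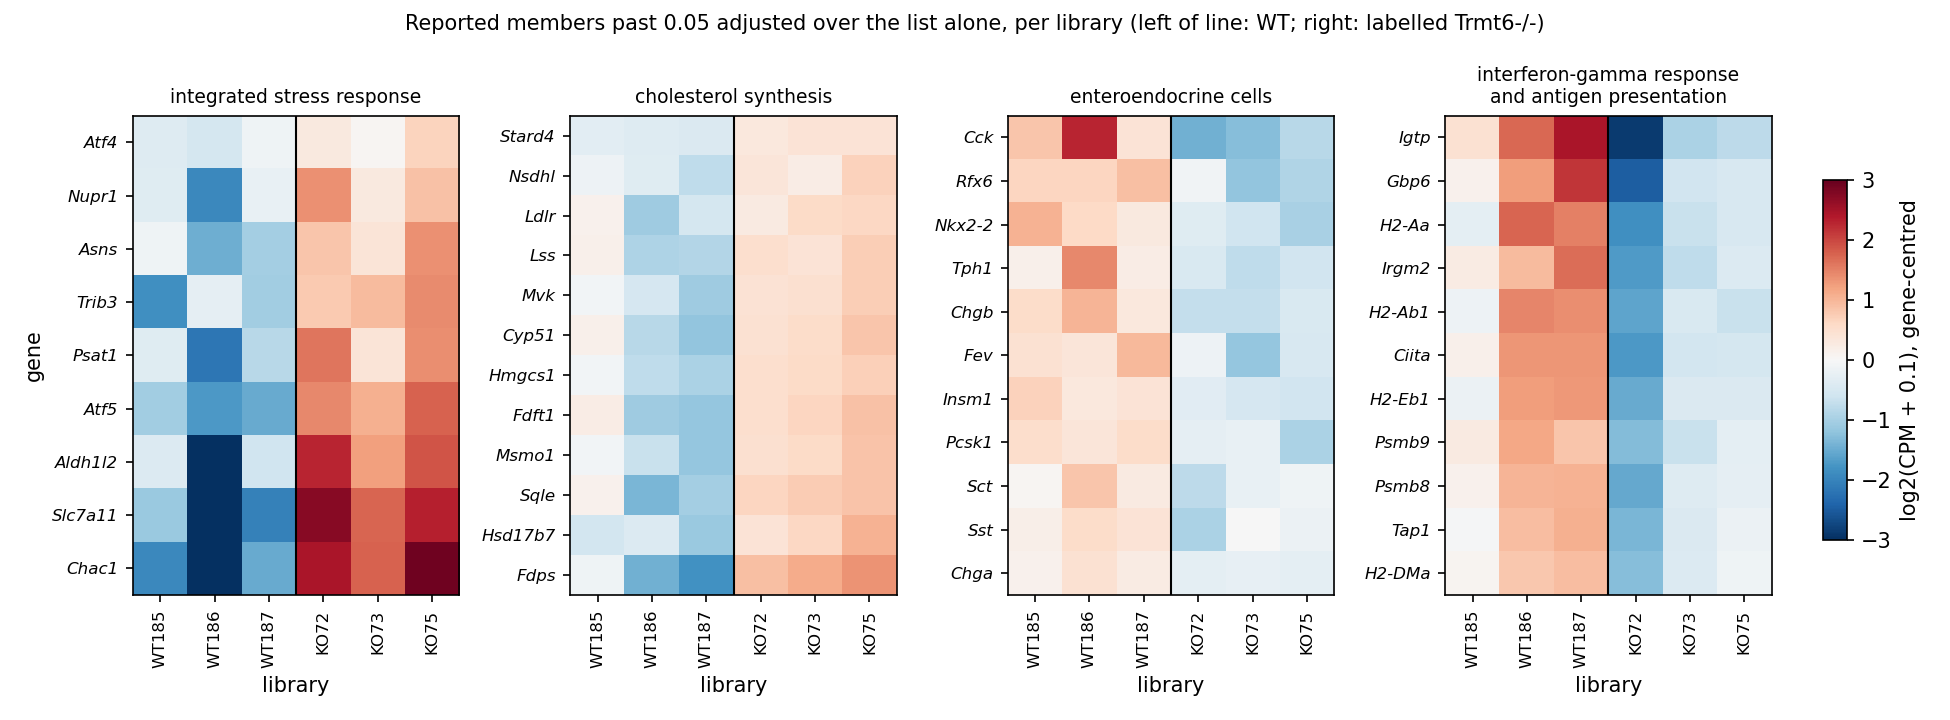
Reported members past 0.05 adjusted over the list alone in 4 lists (rows) across the 6 libraries (columns, WT left of the line), coloured by log2(CPM + 0.1) minus the mean of each gene, with colours ending at 3 on either side of 0. Members of the integrated stress response and cholesterol synthesis lists were higher, and those of the enteroendocrine and antigen presentation lists lower, in the libraries labelled Trmt6-/-, and WT185 was the nearest WT library to their mean for all 11 antigen presentation members drawn.

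Enteroendocrine cell markers fell in the libraries labelled Trmt6-/-. Of 17 members, 11 fell and 0 rose adjusted over the list alone (median -0.96, adjusted p = 8.5e-10; adjusted p = 0.0839 with an estimated correlation). The granule protein genes Chgb (-1.27 ± 0.21; 66.7 ± 6.91 against 161 ± 40.7 CPM) and Chga (-0.56 ± 0.14; 56.9 ± 1.14 against 84.1 ± 10.1 CPM) were among them. So were the hormone gene Cck (-2.59 ± 0.52; 6.94 ± 1.61 against 41.7 ± 30.2 CPM), the prohormone convertase gene Pcsk1 (-0.93 ± 0.25) and the lineage transcription factor genes Insm1 (-0.96 ± 0.25) and Rfx6 (-1.42 ± 0.38). The count in either direction was 0 without KO73, 2 (lower) without KO75, 5 (lower) without WT187, 10 (lower) without KO72 or WT186 and 10 (1 higher, 9 lower) without WT185. It was 7, all lower, with the regional index as covariate, and 9 to 15 under other fits. Chgb lies beside Trmt6 on chromosome 2, at 132781278 to 132795079. Within 10 Mb of Trmt6, 15 of 105 genes (14.3%) had an unadjusted p below 0.05, against 12.1% elsewhere (two-sided Fisher's exact p = 0.454).

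Epithelial defence and repair genes were higher in the libraries labelled Trmt6-/-. In the antimicrobial and acute-phase list, 8 of 22 members rose and 1 fell adjusted over the list alone (median 0.96, adjusted p = 2.0e-06; adjusted p = 0.206 with an estimated correlation). The lectin genes Reg3b (3.18 ± 1.01; 16034 ± 12654 against 1767 ± 1785 CPM) and Reg3g (3.23 ± 0.90; 8390.1 ± 6757 against 893 ± 761 CPM) rose. So did the NADPH oxidase gene Duox2 (2.60 ± 0.87; 565 ± 74.4 against 93.2 ± 89.4 CPM) with its maturation factor Duoxa2 (3.21 ± 0.88; 79.5 ± 6.08 against 8.51 ± 9.52 CPM). Lcn2 (10.3 ± 9.996 against 0.0547 ± 0.0523 CPM; 442 counts against 3, a ratio of 162 with a 95% exact counting interval of 54.9 to 786) and Saa3 (4.31 ± 1.18) also rose. Pigr, the transporter of secretory immunoglobulins, fell (-1.75 ± 0.36; 2256 ± 315 against 7598 ± 2420.2 CPM). Dmbt1 was measured at 6181 ± 2907 against 4076 ± 1817 CPM. By library, Reg3b stood at 4506, 14022 and 29574 CPM in KO72, KO73 and KO75 and at 3806, 487 and 1008 CPM in WT185, WT186 and WT187. KO72 thus lay near WT185, and Reg3b did not pass over all genes (adjusted p = 0.288). The count in either direction was 1 (higher) without KO73, 2 (higher) without KO75, 3 (2 higher, 1 lower) without WT187, 6 (5 higher, 1 lower) without KO72 or WT186 and 11 (9 higher, 2 lower) without WT185. It was 8 (6 higher, 2 lower) with the regional index as covariate, and 8 to 12 under other fits. Markers of regenerating, fetal-like epithelium, which appear during repair of the injured gut, rose in 6 of 15 members (median 1.34, adjusted p = 1.2e-06; adjusted p = 0.206 with an estimated correlation), again adjusted over the list alone. These included S100a6 (2.66 ± 0.36; 79.9 ± 38.6 against 12.6 ± 1.27 CPM), Clu (3.63 ± 0.83; 23.4 ± 10.6 against 1.92 ± 2.18 CPM), Anxa1 (2.11 ± 0.45) and Sprr1a (1.97 ± 0.54). Krt7 was measured at 75.2 ± 33.4 against 51.4 ± 22.2 CPM and Hbegf at 35.6 ± 19.7 against 64.5 ± 60.5 CPM, and the count in either direction was 1 (higher) without WT187, 3 (higher) without WT186, 5 (higher) without KO73 or KO75, 6 (5 higher, 1 lower) without KO72 and 6 (higher) without WT185. With the regional index as covariate it was 3, at a list median of 0.89, and it was 3 to 9 under other fits.

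Goblet cell genes passed toward higher expression, with all 19 members above 0 (median 0.50, adjusted p = 7.5e-07; adjusted p = 0.359 with an estimated correlation). Bcas1 (1.29 ± 0.22; 39.2 ± 2.15 against 16.03 ± 4.43 CPM) and the mucin glycosyltransferase gene B3gnt6 (1.85 ± 0.45; 3.58 ± 0.529 against 0.979 ± 0.492 CPM) rose adjusted over the list alone. Zg16 was measured at 1851 ± 534 against 1160.0 ± 352 CPM. The count was 1 without KO72, KO73, KO75 or WT186, 2 without WT187 and 3 without WT185. It was 0 to 4 under other fits, and the list did not pass with the regional index as covariate (adjusted p = 0.0615). Absorptive colonocyte genes passed with a median of 0.48 and a mean of 0.053 (23 tested, 18 above 0, adjusted p = 0.00343; adjusted p = 0.503 with an estimated correlation), and 0 members passed alone. The count was 0 without KO72, KO73 or KO75, 1 (lower) without WT187, 1 (higher) without WT185 and 3 (higher) without WT186, 8 with the regional index as covariate and 0 to 8 under other fits. The list did not pass without WT187 (0.0906). Lypd8 stood at 3383 ± 1689.7 against 1791 ± 275 CPM and Vil1 at 2924 ± 608 against 2896 ± 1122 CPM. The list does not place the tissue in the colon, as the ileal index marker Slc51b is among its members. Which cells expressed these genes was not tested. Small intestinal enterocyte genes did not pass (20 tested, adjusted p = 0.871), with a median of 0.079, a mean of -0.25 and a test direction toward higher expression. The list passed in that direction without WT186 (0.0464) and with the regional index as covariate (adjusted p = 3.5e-04). In this list 0 members passed alone, with 0 to 4 under other fits. Without WT185, 2 members were higher and 4 lower, and the test direction turned toward lower expression without passing (adjusted p = 0.280). Tight junction and adhesion genes passed narrowly (26 tested, median 0.17, adjusted p = 0.0336; adjusted p = 0.724 with an estimated correlation) with 0 members alone. Cdh17 stood at 2164 ± 271 against 1729 ± 459 CPM and Epcam at 1583 ± 250.0 against 1446 ± 147 CPM. The list did not pass without KO72 (0.0876), KO73 (0.182) or WT186 (0.0941), with the regional index as covariate (adjusted p = 0.630) or with the leukocyte index (adjusted p = 0.147). It did not pass with library totals either (adjusted p = 0.0663).

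Cell cycle genes passed toward lower expression, with 29 of 30 members below 0 (median -0.48, adjusted p = 0.00119; adjusted p = 0.869 with an estimated correlation), but none passed adjusted over the list alone. The list did not pass without KO75 (0.474) or WT185 (0.309). Mki67 stood at 191 ± 96.2 against 287 ± 114 CPM and Top2a at 154 ± 81.8 against 223 ± 93.4 CPM. With the regional index as covariate all 30 passed alone in that direction (adjusted p = 2.6e-25). Mki67 stood at 287, 190 and 94.4 CPM in KO72, KO73 and KO75, in the order of that index (0.61, -1.004 and -3.67). WT185, WT187 and WT186 kept this order too, with 387, 311 and 163 CPM at an index of -1.69, -6.04 and -7.41. Olfm4 kept the same order within each group. The covariate thus also followed the level of these genes, so calls under it cannot be tied to genotype alone. Crypt stem cell and Wnt target genes did not pass (19 tested, median -0.16, adjusted p = 0.124). Olfm4 was measured at 263 ± 239 against 893 ± 593 CPM and Slc12a2 at 278 ± 212 against 309 ± 207 CPM. With that covariate 14 of the 19 passed alone (adjusted p = 2.3e-15), and the list passed toward lower expression without KO72 (1.3e-04) or WT186 (4.9e-04) and with the leukocyte index (adjusted p = 1.8e-04). Paneth cell genes (13 tested, median 0.28, adjusted p = 0.0778) and tuft cell genes (12 tested, median -0.22, adjusted p = 0.300) did not pass. The Paneth list passed toward higher expression without KO73 (0.0131), KO75 (0.0487) or WT185 (2.0e-06), with limma-voom (adjusted p = 0.0374) and with no low-count filter (adjusted p = 0.0319). It passed toward lower expression with the covariate (adjusted p = 0.0392). The tuft list passed toward lower expression without KO73 (0.0394), with the regional index (adjusted p = 0.0373) and with the leukocyte index (adjusted p = 0.00549). Lyz1 was measured at 2093 ± 567 against 2072 ± 1949 CPM, Defa24 at 1620.1 ± 686 against 1039 ± 890.2 CPM, Ptpn18 at 28.9 ± 0.459 against 30.05 ± 7.72 CPM and Trpm5 at 13.5 ± 7.79 against 17.2 ± 2.73 CPM.

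Genes of pyroptosis and necroptosis passed toward higher expression (19 tested, median 0.39, adjusted p = 0.00170; adjusted p = 0.206 with an estimated correlation). Naip1, a sensor of bacterial proteins (1.22 ± 0.17; 244 ± 34.1 against 105 ± 7.74 CPM), and the necroptosis kinase gene Ripk3 (0.96 ± 0.21; 64.02 ± 10.02 against 32.9 ± 7.44 CPM) rose adjusted over the list alone. The DNA sensor gene Aim2 (1.63 ± 0.41; 23.1 ± 6.53 against 7.45 ± 3.63 CPM) rose as well, and 16 did not pass. Naip6 was measured at 632 ± 39.6 against 355 ± 171 CPM and Gsdmd at 649 ± 247 against 334 ± 187 CPM. Naip genes are near-identical copies in a cluster on chromosome 13, so their separate counts are uncertain. The count of members was 1 without KO72, KO73, KO75 or WT187 and 3 without WT185 or WT186. It was 5 with the regional index as covariate and 1 to 6 under other fits. Targets of p53 and apoptosis genes did not pass (18 tested, adjusted p = 0.897; median 0.084, mean -0.074, test direction toward higher expression), and 0 members passed alone. That count was 0 without KO72, KO73, KO75 or WT187, 1 (lower) without WT186 and 3 (1 higher, 2 lower) without WT185. It was 0 to 4 under other fits, in both directions. Cdkn1a stood at 188 ± 23.8 against 159.7 ± 60.9 CPM. Immediate early and heat shock genes passed toward lower expression (22 tested, median -0.61, adjusted p = 0.00219; adjusted p = 0.794 with an estimated correlation). The near-identical heat shock genes Hspa1a (-4.40 ± 0.86; 0.680 ± 0.344 against 14.6 ± 13.03 CPM) and Hspa1b (-3.50 ± 0.71; 3.99 ± 1.61 against 45.2 ± 32.97 CPM) fell adjusted over the list alone. Fos was measured at 435 ± 121 against 547 ± 502 CPM and Hsp90aa1 at 209.5 ± 22.5 against 398 ± 191 CPM. The count was 0 without KO72, KO73, KO75 or WT187, 2 without WT185 and 5 without WT186. It was 4 with the regional index as covariate and 0 to 7 under other fits. Without WT187 the list turned toward higher expression without passing (adjusted p = 0.965, median 0.41). It did not pass with the leukocyte index as covariate (adjusted p = 0.0538, 0 members alone).

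Markers of other cell types were sparse and did not pass as groups. They covered monocytes and macrophages (13 tested, median -0.29, adjusted p = 0.865), B and plasma cells (9 tested, median -0.39, adjusted p = 0.571), mast cells (4 tested, median 0.94, adjusted p = 0.243) and endothelium (6 tested, median 0.61, adjusted p = 0.154). The others were smooth muscle (6 tested, median 0.067, adjusted p = 0.871), adipocytes (3 tested, median -0.33, adjusted p = 0.871), pancreatic acinar cells (4 tested, median -0.11, adjusted p = 0.897) and squamous epithelium (5 tested, median 0.26, adjusted p = 0.414). Fibroblast and matrix genes (6 tested, median 0.085, adjusted p = 0.871) had a mean of -0.093 and a test direction toward lower expression, opposite to their median. The endothelial list passed toward higher expression without KO75 (0.0110), WT185 (0.0138) or WT187 (0.0324). With no low-count filter the endothelial (adjusted p = 0.01003) and mast cell (adjusted p = 0.0165) lists passed toward higher and the acinar list (adjusted p = 0.0113) toward lower expression. The most abundant members of these lists follow, and which cells expressed them was not tested. Plac8 stood at 1115 ± 512 against 1193 ± 535 CPM, Txndc5 at 225 ± 30.03 against 189.9 ± 61.2 CPM, and Igha at 12.6 ± 4.12 against 25.9 ± 10.1 CPM. Kit stood at 35.8 ± 9.69 against 31.3 ± 16.7 CPM and Mcpt1 at 9.89 ± 8.35 against 5.23 ± 2.33 CPM. Lyve1 was measured at 7.30 ± 2.02 against 4.69 ± 0.944 CPM, and Prox1 at 4.22 ± 1.46 against 2.82 ± 0.856 CPM. Mylk stood at 175 ± 17.8 against 274 ± 88.8 CPM and Ldb3 at 109.8 ± 11.5 against 107 ± 47.9 CPM. Pck1 was measured at 151 ± 104 against 272 ± 212 CPM and Cidec at 48.6 ± 16.8 against 48.8 ± 44.8 CPM. Thbs1 stood at 5.24 ± 4.78 against 7.72 ± 7.33 CPM and Dcn at 5.21 ± 3.02 against 3.47 ± 0.562 CPM. Clps was measured at 37.3 ± 19.8 against 29.6 ± 21.1 CPM, and Cela1 at 17.2 ± 7.67 against 10.9 ± 4.63 CPM. Perp stood at 273 ± 27.1 against 205 ± 26.1 CPM and Sfn at 147 ± 8.33 against 137 ± 32.8 CPM. Enteric neuron and glia genes did not pass as a group (4 tested, median -0.61, adjusted p = 0.649). Adjusted over the list alone, 1 member rose and 2 fell. The receptor gene Ret rose (2.44 ± 0.40; 27.7 ± 13.2 against 5.10 ± 0.970 CPM) and Snap25 fell (0.451 ± 0.0492 against 1.97 ± 1.03 CPM).

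The remaining lists were kept outside the tested family. Of 22 neutrophil genes 2 could be tested, Pglyrp1 (110.4 ± 5.32 against 59.4 ± 35.8 CPM) and G0s2 (1.68 ± 1.76 against 2.28 ± 3.46 CPM), and no gene of the distal colon Hox list was abundant enough to test. Haemoglobin and other erythrocyte genes had a median of 1.88 over 5 genes, none past the threshold over all genes or the list alone. The median was 0.71 without KO73. Adjusted over the list alone, 4 passed without KO75, 3 without WT185 or with sample quality weights, and all 5 with DESeq2 or no low-count filter. Hbb-bs was measured at 47.4 ± 42.5 against 14.1 ± 11.2 CPM and Hba-a1 at 34.5 ± 34.005 against 7.55 ± 4.68 CPM. Xist was measured at 945 ± 149 against 920.1 ± 159 CPM (adjusted p = 0.972), and no library had a count from a Y-linked gene of the list. Genes of the mitochondrial chromosome were listed with 0 counts in all 6 libraries.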

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

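The 6 changed genes kept their sign under each alternative fit, and the number past the threshold moved with most of them. RLE size factors, robust dispersions, the stricter filter and a 2-fold minimum each gave 6 genes, and upper-quartile scaling 4 (3 higher, 1 lower). Library totals, which shifted the median of all genes to -0.11, and limma-voom gave 0 genes (0 higher and 0 lower each, 1702 and 1646 at an unadjusted p below 0.05). DESeq2 gave 553 (328 higher, 225 lower), limma-voom with sample quality weights 385 (273 and 112), and no low-count filter 159 (107 and 52), each with all 6 among them. The regional and leukocyte indices as covariates were chosen after seeing the data. The regional index gave 0 (0 higher and 0 lower, 2898 at an unadjusted p below 0.05) and the leukocyte index 2 (2 and 0), of which 1 was among the 6. With a library left out the count ran from 0 to 6 (0 to 6 higher, 0 to 0 lower), with 0 without KO73, KO75, WT186 or WT187, 2 without WT185 (none of the 6) and 6 without KO72 (2 of the 6). Unadjusted p below 0.05 then held for 1047 to 2109 genes. Fewer samples lower the power of each of these fits, and for the other alternatives the cause was not tested. Trmt6 kept a log2 fold change above 0 under every alternative run, from 0.31 to 0.84. Of 38 lists, 19 were called, and alternatives to the fit called 16 to 24, with 11 of the 19 kept in direction and call with the regional index and 15 to 19 otherwise. An estimated correlation called 0 (6 of the 19 at an unadjusted p below 0.05) and fry 1. No paired analysis was possible because the library columns carry no replicate number, so the planned replicate block was not run. In counts simulated with the means and dispersions of these libraries, 16% of genes with a 2-fold change and 92% with a 4-fold change were recovered. The simulated genes varied independently and without regional differences, so this sets no bound on what 3 animals a group detect. The values named below are for genes and lists whose sign turned, 115 of 2410 alternative values for genes, 0 of them with a call in either fit, and 65 of 722 for lists, 11 of them with such a call. In each, the cause was not tested.

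With library totals, the log2 fold change turned sign for Nsun2 at -0.080, Hspa5 at -0.078, Vil1 at -0.030, Lyz1 at -0.13 and Xist at -0.035. The list that turned under library totals, with its adjusted p, was p53 targets and apoptosis (0.976). With sample quality weights, the log2 fold change turned sign for Nsun2 at -0.0061, Hspa5 at -0.030, Ptpn18 at 0.16, G0s2 at 1.38, Kit at -0.074, Mcpt1 at -0.13, Cidec at 0.73 and Sfn at -0.067. It also turned for Pdx1 at 1.07 and Trmt61a at -0.0079. Lists that turned under sample quality weights, with adjusted p, were tuft cells (0.507), adipocytes (0.480), pancreatic acinar cells (0.929), p53 targets and apoptosis (0.801) and fatty acid oxidation and ketogenesis (0.235). With the regional index, the log2 fold change turned sign for Nsun2 at -0.46, Elp2 at -0.025, Lyz1 at -0.65, Defa24 at -0.31, Ptpn18 at 0.11, Krt7 at -0.31, Epcam at -0.00062 and Ccl5 at 0.43. It also turned for Lif at 0.27, G0s2 at 2.58, Plac8 at 0.75, Gzma at 0.51, Cd8a at 1.06, Txndc5 at -0.024, Kit at -0.41 and Prox1 at -0.039. So did those of Pck1 at 0.35, Cidec at 1.54, Clps at -0.71, Ifih1 at 0.039, Stat2 at 0.16, H2-K1 at 0.13, Atp5a1 at 0.040 and Fos at 0.14. The others under it were Xist at -0.26, Fabp6 at -1.98 and Trmt61a at -0.47. Lists that turned under the regional index, with adjusted p, were tRNA modification enzymes (0.0173), cytosolic ribosomal proteins (0.838), translation factors (0.545), Paneth cells (0.0392) and inflammatory cytokines and chemokines (0.688). To these are added monocytes and macrophages (0.155), T and NK cells (0.110), fibroblasts and extracellular matrix (0.886), adipocytes (0.307) and fatty acid oxidation and ketogenesis (0.00536). To these are added oxidative phosphorylation (nuclear) (0.764). With the leukocyte index, the log2 fold change turned sign for Nsun2 at -0.12, Lyz1 at -0.10, Lif at 0.0072, Cd8a at 0.35, Cidec at 0.026, Clps at -0.043, Fos at 0.17 and Xist at -0.063. It also turned for Trmt61a at -0.027. Lists that turned under the leukocyte index, with adjusted p, were tRNA modification enzymes (0.741), monocytes and macrophages (0.835), fibroblasts and extracellular matrix (0.976) and fatty acid oxidation and ketogenesis (0.976). With limma-voom, the log2 fold change turned sign for G0s2 at 0.58, Thbs1 at 0.23, Cidec at 0.36 and Fos at 0.0044. Lists that turned under limma-voom, with adjusted p, were adipocytes (0.950) and pancreatic acinar cells (0.941). With upper-quartile scaling, the log2 fold change turned sign for Cidec at 0.038. With no low-count filter, the log2 fold change turned sign for Cidec at 0.0064. Lists that turned under no low-count filter, with adjusted p, were B and plasma cells (0.502), fibroblasts and extracellular matrix (0.921), adipocytes (0.242) and p53 targets and apoptosis (0.829). Lists that turned under DESeq2, with adjusted p, were small intestinal enterocytes (0.770), fibroblasts and extracellular matrix (0.943), enteric neurons and glia (0.943) and p53 targets and apoptosis (0.950). The list that turned under the stricter filter, with its adjusted p, was enteric neurons and glia (0.250).

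With each library left out in turn, the log2 fold change took either sign for Nsun2 from -0.17 to 0.27, Hspa5 from -0.25 to 0.22, Vil1 from -0.24 to 0.31, Lyz1 from -0.44 to 1.13 and Ptpn18 from -0.20 to 0.18. Other ranges were Trpm5 from -0.73 to 0.063, Slc12a2 from -0.87 to 0.52, Hbegf from -1.37 to 0.17, Ccl5 from -1.78 to 0.14 and Lif from -0.19 to 0.061. The range for the following genes was G0s2 from -1.74 to 2.57, Plac8 from -0.51 to 0.33, Gzma from -1.78 to 0.11, Cd8a from -1.12 to 0.63 and Kit from -0.18 to 0.55. Further genes ranged as follows, Mcpt1 from -0.038 to 1.28, Thbs1 from -1.61 to 0.30, Ldb3 from -0.20 to 0.45, Cidec from -0.39 to 1.09 and Clps from -0.20 to 1.10. Ranges were also wide for Sfn from -0.017 to 0.30, Cdkn1a from -0.0069 to 0.54, Fabp1 from -0.72 to 1.247, Gapdh from -0.035 to 0.49 and Fos from -0.69 to 0.74. Other ranges were Xist from -0.094 to 0.21, Naip5 from -0.027 to 0.29, Fabp6 from -0.43 to 7.30 and Trmt61a from -0.19 to 0.51. Lists whose direction turned in at least 1 of these fits had adjusted p running for tRNA modification enzymes from 0.0812 to 0.965, unfolded protein response from 0.300 to 0.965 and small intestinal enterocytes from 0.0464 to 0.987. Adjusted p ran for Paneth cells from 2.0e-06 to 0.659, tuft cells from 0.0394 to 0.873 and crypt stem cells and Wnt targets from 1.3e-04 to 0.933. For other such lists it ran for monocytes and macrophages from 0.178 to 0.928, T and NK cells from 3.3e-08 to 0.821 and B and plasma cells from 0.327 to 0.798. Adjusted p ran for smooth muscle from 0.491 to 0.912, adipocytes from 0.110 to 0.936 and pancreatic acinar cells from 0.529 to 0.987. For other such lists it ran for p53 targets and apoptosis from 0.294 to 0.987, fatty acid oxidation and ketogenesis from 0.0262 to 0.627 and immediate early and heat shock from 2.2e-07 to 0.965.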

Other observations

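The 3 tests on Trmt6 and the test of intestinal position for the integrated stress response were chosen after those results were seen, as were the genes named in the first 2 paragraphs. The regional and leukocyte indices used in every covariate test below were also chosen after seeing the data.

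In the Ly6 cluster on chromosome 15, where Ly6d and Gml2 passed the threshold, Gml stood at 23.3 ± 9.82 against 0.254 ± 0.329 CPM (1036 counts against 14, ratio 81.1, 95% exact counting interval 48.1 to 149; adjusted p = 0.112) without passing. Ly6e of the same cluster was measured at 96.6 ± 16.1 against 115 ± 11.6 CPM (adjusted p = 0.631), with overlapping groups. The cluster was not tested as a group. Eif4ebp1, which encodes an inhibitor of cap-dependent translation, stood at 40.3 ± 2.13 against 8.29 ± 4.04 CPM (adjusted p = 0.112). The peptide hormone gene Adm2 stood at 3.13 ± 0.721 against 0.0547 ± 0.0523 CPM (146 counts against 3, ratio 53.4, 95% exact counting interval 17.9 to 262; adjusted p = 0.0838). Of further members of the Naip cluster, Naip3 was measured at 30.2 ± 4.71 against 11.3 ± 1.47 CPM (adjusted p = 0.112) and Naip5 at 376 ± 34.5 against 344 ± 84.9 CPM (adjusted p = 0.887).

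Of transcription factor genes of the proximal intestine, Onecut2 was measured at 27.5 ± 20.4 against 156 ± 105 CPM (adjusted p = 0.239) and Pdx1 at 0.611 ± 0.291 against 17.8 ± 20.1 CPM (27 counts against 843; adjusted p = 0.307). The Pdx1 groups overlapped, with 261 counts in WT185, 581 in WT186 and 1 in WT187.

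Trmt6 transcript was not lower in the libraries labelled Trmt6-/-. An exchange of the group labels with a deletion that abolishes the transcript would leave the lower group near 0, and it stood at 66.0% of the other. Counts from an overlapping gene were also argued against, since 0% of the Trmt6 exon bases are shared. A deletion that leaves most of the transcript in place may account for the absence of a fall, and stays open because gene totals cannot show exons. With such a deletion an exchange of the labels stays open too, as the test above covers only an abolished transcript. Exon-level coverage could show whether exons are missing and in which libraries, and would not decide the question where none is missing. The log2 fold change of 0.60 did not pass the test, and no explanation of a rise was tested.

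The integrated stress response list was higher in the libraries labelled Trmt6-/-, in which Trmt6 was not lower. It passed with camera at the preset correlation, and not with an estimated correlation (adjusted p = 0.206) or with fry (adjusted p = 0.0993). At the preset correlation and with the regional index as covariate its median log2 fold change was 0.65, from 0.83 without it (adjusted p = 4.8e-07). With that covariate 7 members passed alone, from 9, which argues against position, as this index measures it, as the whole cause. The index markers did not all rank the libraries alike, so position that the index misses stays open. With the leukocyte index the median was 0.80 (adjusted p = 9.3e-13), which argues against the share of T and NK cells as the whole cause. Other leukocytes were not part of that index. A response tied to genotype may remain, as a hypothesis found and tested on the same 6 libraries, and a difference in how far colitis had advanced was not tested.

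The interferon-gamma response and antigen presentation list was lower in the libraries labelled Trmt6-/-. It passed with camera at the preset correlation, and not with an estimated correlation (adjusted p = 0.446) or with fry (adjusted p = 0.279). At the preset correlation and with the leukocyte index its median log2 fold change was -0.76, from -1.18 (adjusted p = 4.1e-12). With that index 12 members passed alone, from 11, which argues against the share of T and NK cells as the whole cause. Other leukocytes were not part of it. With the regional index the median was -0.34 (adjusted p = 0.0135) and no member passed adjusted over the list alone, where 11 had. Position along the intestine and genotype cannot be told apart for this list, because WT186 and WT187 had the lowest regional index and the highest H2-Aa. Effects of genotype on these genes may be present, and libraries from a matched segment would be needed.

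The 6 libraries can be divided into 3 and 3 in 10 ways, so the share of splits with a result as large cannot go below 0.1. The real split gave 6 genes and the highest of the others 0, so 1 of 10 reached it. It called 19 lists and the highest of the others also 19, so 4 of 10 reached it. At an unadjusted p below 0.05 the real split had 1706 genes, KO72, WT185 and WT187 against the rest had 2059, and KO72, KO73 and WT185 against the rest had 1818. With DESeq2 these 3 splits gave 553, 351 and 231 genes. The last 2 put KO72 and WT185 together, but so did 2 splits with 736 and 518 genes (6 and 2 with DESeq2), so the pairing alone does not account for these splits. KO72, KO73 and WT185 were the 3 libraries with the highest regional index, and their split coincides with that index. In the other split, KO72, WT185 and WT187 carried more Mki67 (287, 387 and 311 CPM) than KO73, KO75 and WT186 (190, 94.4 and 163 CPM). Top2a followed, at 238, 292 and 261 CPM against 148, 75.1 and 117 CPM. KO72, WT185 and WT187 also had higher TMM factors, at 1.04 to 1.13 against 0.91 to 0.94. That split thus coincides with the level of these cell cycle genes, and its cause was not tested. Within each group these genes also followed the order of the regional index, so that index and their level are not independent. The real split had 9 members of the integrated stress response list past the threshold adjusted over the list alone, 13 of cholesterol synthesis, 11 of the enteroendocrine list and 11 of the antigen presentation list. The highest of the other splits had 0, 0, 0 and 1. Other lists went the opposite way, with up to 29 members in another split against 0 for cell cycle, 17 against 0 for T and NK cells and 12 against 0 for crypt stem cells. Fatty acid oxidation had up to 11 against 1 and small intestinal enterocytes up to 6 against 0. Camera gave cholesterol synthesis a smaller p in another split (1.1e-22) than in the real one (2.7e-17). Among called lists its smallest p fell in the real split for integrated stress response, goblet cells, enteroendocrine cells and regenerating epithelium. It did so too for antigen presentation (7.6e-17 against 8.2e-17), pyroptosis and necroptosis, and hypoxia and glycolysis. All other called lists had a smaller p in another split, such as cell cycle (5.5e-37 against 4.1e-04) and cytosolic ribosomal proteins (4.5e-26 against 3.2e-08). List medians as large were found in 2 of 10 splits for the integrated stress response and for antigen presentation, and in 1 of 10 for cholesterol synthesis and enteroendocrine cells.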
